A study of Arabidopsis thaliana with 18 samples.

How the data were processed

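Gene expression was measured on 18 Arabidopsis ATH1 arrays, 3 for each of 6 groups: protoplasts transformed with an empty vector, IAA7mII or IAA19mII, each treated with IAA or solvent. Per the labels, seedlings of the Columbia line with a green reporter under the WEREWOLF promoter were grown for 7 days, roots were digested to protoplasts for 3 h, and the cells were transformed with polyethylene glycol and left overnight before treatment. Cells with both green and red fluorescence were sorted straight into RNA extraction buffer, and RNA was amplified with the NuGEN WT-Ovation Pico kit. The empty vector is a different plasmid (pMON999_mRFP) from the backbone of both over-expressors (pBeaconRFP), so comparisons with the empty vector also hold the backbone.

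The values are MAS5 signal intensity per probeset on a linear scale, as deposited by the authors; the submitters' processing notes name MAS5, and its version is not given in the sources used here. The arrays had been scaled alike: their trimmed means (2% trim) lay between 246 and 248, while their 75th percentiles were 264 to 275 in the empty vector arrays and 220 to 238 in the over-expressor arrays. That scaling was kept. Pairs of arrays within a group had Pearson correlations of 0.918 to 0.973 across probesets, and no pair of arrays was identical. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision.

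Of 22746 probesets, the 16892 above their array's 40th percentile on at least 3 of the 18 arrays were tested. Gene names come from the probe table supplied for this platform, joined to a reference gene table of assembly TAIR10.1 by gene identifier, used for names only. Of the 22746 probesets 13513 carry 1 gene in that table, 13436 of them matched in the reference table, 503 carry several and 8730 carry none; among those tested, 9509, 376 and 7007. Genes without a named probeset were not analysed here. One probeset per gene, the one with the highest mean, stood for a gene.

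Log2(signal + 16) was fitted with limma 3.58.1 in R 4.3.3 with 1 mean per group and an empirical Bayes prior with an intensity trend. The 12 comparisons were the 3 responses to IAA, the 3 differences between responses, and the 6 comparisons between vectors within mock or IAA. Benjamini-Hochberg adjustment was made within each comparison, and a probeset was called at an adjusted p under 0.05. The groups, comparisons, filter, fixed gene lists, alternatives and the rule for naming genes were set before the data were examined. The rule named the transgenes, the 10 called single-gene probesets with the largest change in each direction among those without overlap between groups (for differences of responses, called only), and from each fixed list up to 4 called members, or up to 2 uncalled members given as values.

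Gene lists were tested with limma's camera with a preset correlation of 0.01, with camera and an estimated correlation, and with fry beside it, adjusted over lists within each comparison. The 25 fixed lists had at least 3 tested members in 5 cases and none in 10. A further 16 lists were chosen after the annotation was seen and before group differences were, and are given in the closing section. The auxin index is the mean of the 8 tested members of the early auxin list, compared by exact two-sided permutation; for differences of responses vector labels were permuted within each treatment, giving 400 assignments. The plan had counted these as 10 by 10 splits.

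The procedure was tested on simulated data with changes added to 200 probesets of 16892. For the response in empty vector cells, 17 of 100 changes of log2 1 and 85 of 100 of log2 2 were recovered with 3 false calls. For the difference in response between IAA7mII and empty vector, 7 and 47 of 100 were recovered, with 3 false calls. The simulated groups had equal spread and no differences between vectors in mock. The real median SD was 0.26 and 0.29 in the empty vector groups and 0.35 to 0.44 in the over-expressor groups. These figures may therefore not hold for comparisons that include over-expressor cells. The shared empty vector arrays were modelled with 50 simulations.

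Alternatives tried were other pseudocounts (1 and 64), no filter or a filter at the 60th percentile, median centring, quantile normalization, no intensity trend, an unmoderated test, array weights, only the groups of a comparison, the replicate number as a block, a minimum 2-fold change, other members of the index, and leaving out each array in turn. Leaving out an array leaves 2 in its group, with the spread pooled over all groups. A list of ribosomal protein genes was not built, since the tables used hold no gene descriptions. The transgenes were not analysed here.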

Results

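Root protoplasts of Arabidopsis seedlings carrying a green fluorescent reporter driven by the WEREWOLF promoter, which is active in the root epidermis and lateral root cap, were transformed with an empty vector or with a plasmid over-expressing IAA7mII or IAA19mII. Each population then received 5 µM of the auxin indole-3-acetic acid (IAA) or its solvent (mock) for 3 h, and cells that were both green and red were sorted for expression arrays. IAA7 and IAA19 are Aux/IAA proteins, a family of repressors of auxin-induced genes that auxin marks for degradation through their domain II; mII is taken here as a mutated domain II, which the labels do not spell out. The 18 arrays make 6 groups of 3 replicates. Signals of 16892 probesets were tested, of which 9509 match a single gene in the annotation used. Values after ± are standard errors of the log2 change unless a standard deviation (SD) is named. These errors are pooled over all 6 groups, though the spread was unequal. The median SD of a probeset was 0.26 and 0.29 in the empty vector groups and 0.35 to 0.44 in the over-expressor groups. Fold changes are on the scale log2(signal + 16) and understate changes of genes with low signals; a difference between responses can be understated or inflated where a mock signal is low.

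The first question was which genes IAA changes in cells with the empty vector (3 mock and 3 IAA arrays). IAA raised GH3.3, whose product joins auxin to amino acids, 87.5-fold (log2 change 6.45 ± 0.44, limma adjusted p = 3.95e-10), from a mean signal of 46.2 (SD 17.3) to 5318 (SD 556). The Aux/IAA genes IAA30 and IAA29 rose 35.9-fold (5.16 ± 0.35) and 34.4-fold (5.1 ± 0.48), and the homeobox gene HAT2 rose 24.1-fold (4.59 ± 0.48). The lateral organ boundaries genes LBD16 and LBD29, which act in lateral root initiation, rose 5.14-fold (2.36 ± 0.41) and 4.1-fold (2.04 ± 0.35). The largest fall was that of AT4G10270, 16.5-fold lower with IAA (-4.05 ± 0.69, limma adjusted p = 0.00152).

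In total 124 probesets changed with IAA in empty vector cells, 56 higher and 68 lower, against 871 at an unadjusted p under 0.05; 57 of them match a single gene and 67 match none or several. Among the other genes with the largest rises and no overlap between the arrays were AT4G37380 (7.65-fold), AT1G60010 (6.75-fold), AT1G64405 (6.3-fold), the peptide gene CLE44 (6.28-fold), AT5G57340 (6.03-fold) and GH9C2 (5.42-fold), an endoglucanase gene by its family. The other large falls were AT3G10040 (5.33-fold lower), AT1G64590 (4.17-fold), AT3G05400 (3.36-fold), AT1G33055 (3.33-fold), AT3G46700 (2.81-fold), AT4G16260 (2.75-fold), AT3G06210 (2.74-fold), AT4G24110 (2.71-fold) and AT4G33980 (2.59-fold). Chance alone leaves 10% of genes without overlap between 3 arrays and 3 arrays. Without empty vector mock replicate 2 the count was 78, and without empty vector IAA replicate 2 it was 81. The count was 328 with array weights, 66 without the intensity trend and 69 with an unmoderated test.

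Of the auxin gene lists only part could be tested here, as several had no tested member. All 8 kept members of the list of early auxin genes were higher (median log2 change 3.47), over all probesets and adjusted over the list alone, and limma's camera test kept the list with an estimated correlation (adjusted p = 1.69e-07). Within the GH3 list GH3.3, GH3.1 (4.36-fold) and WES1 (2.88-fold, 1.53 ± 0.17) rose while GH3.17 fell (1.88-fold lower, -0.91 ± 0.21, limma adjusted p = 0.0269), a fall that lost its call in 8 of 19 other settings. Of the Aux/IAA list 2 of 4 members rose. Camera kept the GH3 list (adjusted p = 1.44e-10, and 7.32e-05 with an estimated correlation) and the Aux/IAA list (2.12e-12, and 2.48e-05). The 9 kept expansin and xyloglucan endotransglucosylase genes had no called member over all probesets and 2 adjusted over the list alone; XTH19 (1.00 ± 0.28) and EXPA16 (1.27 ± 0.38) came closest, and the list's median was 0.06 (-0.04 after quantile normalization; camera adjusted p = 0.0453, and 0.174 with an estimated correlation).

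The next question was how cells over-expressing IAA7mII respond to the same IAA treatment. GH3.3 rose 19.2-fold (log2 change 4.27 ± 0.44, limma adjusted p = 2.05e-06, 3 against 3 arrays) and IAA30 rose 5.39-fold (2.43 ± 0.35). The GH3.3 mean signal went from 5.73 (SD 6.31) to 476 (SD 335). WES1 rose 2.41-fold (1.27 ± 0.17) and AT4G13180 rose 2.57-fold (1.36 ± 0.24). AT5G44720 fell 3.83-fold (-1.94 ± 0.36) and AT3G51940 fell 3.24-fold (-1.69 ± 0.31). HAT2 (1.44 ± 0.48), LBD16 (1.07 ± 0.41) and LBD29 (0.14 ± 0.35) did not pass the test. A total of 15 probesets changed, 12 higher and 3 lower, against 1306 at an unadjusted p under 0.05, and 9 of the 15 match no single gene. The count was 35 without IAA7mII IAA replicate 1. Of the early auxin list 3 members were called and 5 adjusted over the list alone (camera adjusted p = 6.72e-15, and 0.000181 with an estimated correlation). The Aux/IAA list did not pass in this response (camera adjusted p = 0.0778), and the GH3 list did (1.97e-09, and 0.000181 with an estimated correlation).

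In cells over-expressing IAA19mII, IAA raised GH3.3 35.3-fold (log2 change 5.14 ± 0.44, limma adjusted p = 5.70e-08, 3 against 3 arrays). HAT2 rose 6.14-fold (2.62 ± 0.48), IAA30 rose 5.02-fold (2.33 ± 0.35), AT4G13180 rose 2.42-fold (1.28 ± 0.24) and WES1 rose 1.91-fold (0.93 ± 0.17). The single gene called lower was IQD27, 4.0-fold (-2.0 ± 0.38, limma adjusted p = 0.0252). LBD16 (0.28 ± 0.41) and LBD29 (0.18 ± 0.35) did not pass. Again 15 probesets changed, 13 higher and 2 lower, against 1490 at an unadjusted p under 0.05. The count fell to 8 without IAA19mII mock replicate 1, 7 without IAA19mII mock replicate 2 and 8 without IAA19mII IAA replicate 2. The early auxin list had 4 called members and 5 adjusted over the list alone (camera adjusted p = 5.65e-13, and 0.000286 with an estimated correlation). The Aux/IAA list (0.000439, and 0.00577 with an estimated correlation), the GH3 list (1.27e-08, and 0.000286) and the expansin and xyloglucan endotransglucosylase list (median 0.79, 0.000242, and 0.0175) also passed camera in this response.

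The probesets called in empty vector cells moved less in the over-expressors. Their 56 rises had a median log2 change of 2.26 in empty vector cells, 0.87 with IAA7mII and 0.59 with IAA19mII, and 49 and 53 of the 56 were smaller. Their 68 falls had a median of -1.09 in empty vector cells, -0.11 with IAA7mII and -0.12 with IAA19mII, and 0 of the 68 were called in either over-expressor. These probesets were chosen on the empty vector arrays, so the shrinkage is not independent evidence of a smaller response. All 12 probesets raised in IAA7mII cells, and 11 of the 13 raised in IAA19mII cells, were also raised in empty vector cells.

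An auxin index, the mean log2(signal + 16) of the 8 early auxin genes, measured the response of each population with one value per array. In empty vector cells it went from 6.39 (SD 0.23) to 10.06 (SD 0.16), a response of 3.67 ± 0.21 or 12.7-fold. The response was 1.52 ± 0.21 (2.86-fold) with IAA7mII and 1.64 ± 0.21 (3.13-fold) with IAA19mII. Each response had an exact two-sided permutation p = 0.1, the smallest that 3 against 3 arrays allow. The response was smaller than in empty vector cells by a log2 difference of -2.15 ± 0.30 for IAA7mII (exact permutation p = 0.105 over 400 assignments) and -2.02 ± 0.30 for IAA19mII (exact permutation p = 0.1). Vector labels were permuted within each treatment, and because the mock levels differ in the same direction as the IAA levels, all 40 assignments that keep or swap the IAA labels whole reach the observed value; this permutation p could not fall below 0.1 here and says little about the difference of responses. Both differences were several times the pooled SD of 0.258. On this scale all 8 genes responded less in both over-expressors; with a pseudocount of 1 in place of 16 GH3.3 did not with IAA19mII (difference 0.16), leaving 7 of 8. The responses of IAA19mII and IAA7mII cells differed by 0.13 (exact permutation p = 0.76).

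**Figure D1:**
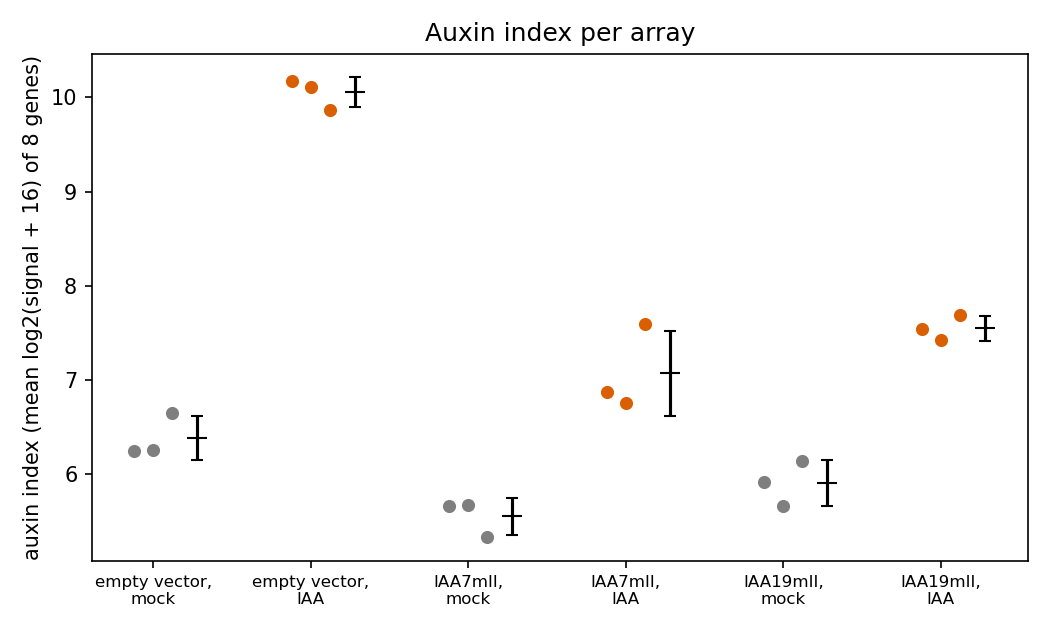
Auxin index per array, the mean log2(signal + 16) of 8 early auxin genes, on the y axis against the 6 groups on the x axis; points are arrays, dashes group means and bars SD. The empty vector mean goes from 6.39 in mock to 10.06 with IAA, that of IAA7mII from 5.55 to 7.07 and that of IAA19mII from 5.90 to 7.55.

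The question behind the next comparison was whether single genes respond differently to IAA when IAA7mII or IAA19mII is over-expressed, tested as the difference between responses in limma. IAA29 responded less in both, by -4.54 ± 0.68 with IAA7mII (limma adjusted p = 0.00165) and -4.54 ± 0.68 with IAA19mII (limma adjusted p = 0.00220), its mean signal with IAA being 1062 in empty vector, 12.9 in IAA7mII and 22.8 in IAA19mII cells. IAA30 also responded less, by -2.73 ± 0.50 and -2.84 ± 0.50. AT1G64405 passed with IAA7mII (-2.98 ± 0.57) and AT4G37380 with IAA19mII (-3.25 ± 0.66), while the values with the other plasmid were similar and not called (-2.77 ± 0.57 and -2.69 ± 0.66). A further set of genes that IAA lowered in empty vector cells were not called in the responses of the over-expressors: AT3G46700 (difference 1.54 ± 0.27 and 1.5 ± 0.27), SFP1 (1.39 ± 0.22 and 1.38 ± 0.22) and AT1G02360 (1.38 ± 0.27 and 1.32 ± 0.27).

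Each of these calls was lost in at least 1 of 25 other settings, IAA29 in 2 and SFP1 in 1 for either plasmid, AT1G02360 in 15 for IAA7mII and 16 for IAA19mII. SFP1 went from a mean signal of 1505 to 602 with IAA in empty vector cells, from 4146 to 4406 with IAA7mII and from 3461 to 3660.2 with IAA19mII. OSM34, an osmotin gene, passed with IAA19mII (1.16 ± 0.23, limma adjusted p = 0.0408) and narrowly missed with IAA7mII (1.12 ± 0.23, limma adjusted p = 0.0604). The difference for HAT2 with IAA7mII was -3.15 ± 0.68 (limma adjusted p = 0.082), and those for GH3.3 (-2.19 ± 0.62), LBD29 (-1.90 ± 0.50) and LBD16 (-1.29 ± 0.59) did not pass either. The GH3.3 value depends on the pseudocount, since its mock mean is 5.73 in IAA7mII cells: it was -0.62 with pseudocount 1 and -2.88 with pseudocount 64, where it passed. With IAA19mII the uncalled values were HAT2 -1.97 ± 0.68, LBD16 -2.08 ± 0.59 and LBD29 -1.86 ± 0.50. In all, 11 probesets differed for IAA7mII (4 higher, 7 lower, against 844 at an unadjusted p under 0.05; 10 and 8 after quantile normalization) and 15 for IAA19mII (8 and 7, against 825). The first count was 6 without empty vector mock replicate 1, 5 without empty vector mock replicate 3, 5 without empty vector IAA replicate 2, 7 without IAA7mII mock replicate 1, 5 without IAA7mII mock replicate 2, 6 without IAA7mII IAA replicate 1 and 7 without IAA7mII IAA replicate 2. The other was 7 without empty vector mock replicate 2 or 3, 8 without empty vector IAA replicate 1, 4 without empty vector IAA replicate 2, 8 without IAA19mII mock replicate 1 or 2 and 9 without IAA19mII IAA replicate 2. The early auxin list was lower in both differences, with 2 members called and 6 adjusted over the list alone in each (camera adjusted p = 5.82e-16 and 8.35e-16, and 0.000139 and 0.000146 with an estimated correlation). The Aux/IAA list passed as well (5.68e-08 and 9.12e-05, and 0.000257 and 0.00313 with an estimated correlation), with 2 of 4 members called in each. The expansin and xyloglucan endotransglucosylase list was lower for IAA7mII by camera (adjusted p = 0.0101) and did not hold with an estimated correlation (0.1).

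**Figure D2:**
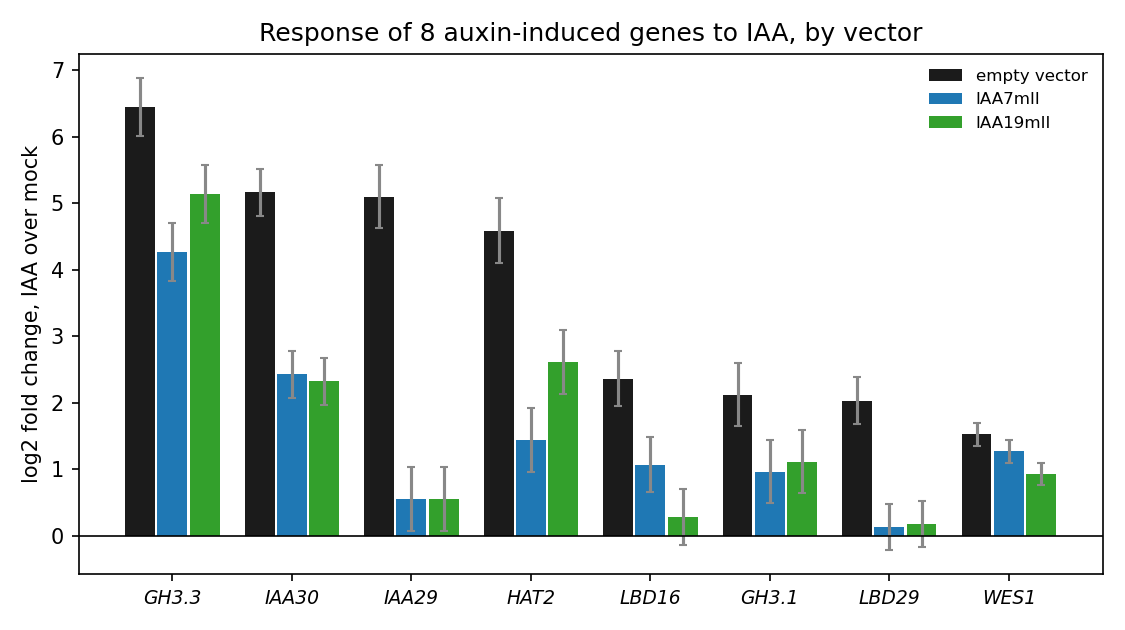
Log2 change with IAA over mock (y axis) of the 8 early auxin genes (x axis) in empty vector, IAA7mII and IAA19mII cells, with 3 arrays per group. Error bars are limma's standard errors, pooled over all 6 groups, so a gene has the same bar in each population. GH3.3 has the tallest bar in each population (6.45, 4.27 and 5.14), and IAA29 drops from 5.1 to 0.56 in both over-expressors.

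The responses of IAA19mII and IAA7mII cells to IAA were compared with each other in the same way. No probeset matching a single gene differed: GH3.3 (0.88 ± 0.62), HAT2 (1.18 ± 0.68), XTH18 (1.33 ± 0.47) and EXPA4 (1.72 ± 0.67) all failed the limma test. The 3 called probesets match no gene in the annotation used, against 1071 at an unadjusted p under 0.05, and without IAA19mII IAA replicate 1 there were 5. Of the 3, 1 was lower and is not identified further, and the other 2 are listed at 0 on all 3 arrays of a group, so no fold is given. Probeset 257769_at read 25590 to 28174 in IAA7mII mock arrays, 0 in IAA7mII IAA arrays and 805 to 1669 elsewhere. Probeset 258399_at read 26034 to 35135 in IAA19mII mock arrays and 0 in IAA19mII IAA arrays, against 629 to 881 in empty vector mock, 4918 to 5699.6 in empty vector IAA, 67.2 to 83.9 in IAA7mII mock and 347 to 988 in IAA7mII IAA arrays. Both identifiers were singled out after their values were seen, and these probesets account for 1 of the 124 calls in the empty vector response, 2 of the 15 in the IAA7mII response, 1 of the 15 in the IAA19mII response and 1 in each difference from the empty vector. The early auxin list did not differ (camera adjusted p = 0.982). The expansin and xyloglucan endotransglucosylase list passed camera (adjusted p = 0.000358) and did not hold with an estimated correlation (0.0551), and no member was called.

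Over-expressing cells were then compared with empty vector cells in mock, to ask what the plasmids change before IAA is added. With IAA7mII, AT1G26390 was 14.4-fold higher (3.85 ± 0.35) and AT4G18425 13.6-fold higher (3.76 ± 0.20, limma adjusted p = 4.28e-13), at a mean signal of 2503 against 172; the purple acid phosphatase gene PAP20 was 7.17-fold higher (2.84 ± 0.24) and scpl28 7.93-fold higher (2.99 ± 0.34). AT3G26590 was 10.8-fold lower (-3.44 ± 0.47), AT3G25930 10.3-fold lower (-3.37 ± 0.43) and FOLB2 5.69-fold lower (-2.51 ± 0.54). The auxin genes GH3.3 (2.87-fold), WES1 (2.59-fold, -1.37 ± 0.17) and IAA30 (2.58-fold) were lower too. The cytokinin response regulator RR16 was 4.39-fold higher (2.13 ± 0.40), XTH18 2.95-fold higher and XTH19 1.83-fold lower, the last lost in 12 of 19 other settings.

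In total 1928 probesets differed between IAA7mII and empty vector cells in mock, 900 higher and 1028 lower. The median over all probesets was shifted by -0.09 on the log2 scale; with arrays centred on their medians the split was 1414 higher and 537 lower, and after quantile normalization 931 and 861. Other genes with large, non-overlapping rises were AT5G64190 (9.83-fold), AT2G16890 (9.53-fold), AT4G09100, AT5G43590, AT2G43880 and AT1G29090; the other falls were AT5G41680 (8.36-fold), AT1G78070 (8.13-fold), AT3G49720, TRM28 (6.81-fold), AT3G27220, AT5G66310 and AT4G10270 (5.52-fold). The count was 1284 without empty vector mock replicate 1 and 1214 without empty vector mock replicate 3. Of the early auxin list 3 members were lower and 4 adjusted over the list alone (camera adjusted p = 0.0121, and 0.17 with an estimated correlation).

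With IAA19mII in mock, cwINV6, a cell wall invertase gene by name, was 70.4-fold higher than in empty vector cells (6.14 ± 0.35, limma adjusted p = 1.66e-12), at a mean signal of 2746 against 23.9, while the IAA7mII mean was 200. AT2G16890 was 31.8-fold higher (4.99 ± 0.36), AT4G18425 13.3-fold higher (3.74 ± 0.20) and scpl28 10.6-fold higher (3.41 ± 0.34). AT1G32860 was 7.5-fold lower (-2.91 ± 0.58) and FOLB2 7.21-fold lower (-2.85 ± 0.54). GH3.17 was 3.14-fold higher (1.65 ± 0.21) and XTH18 2.67-fold higher, while IAA30 was 2.66-fold lower and GH3.3 2.78-fold lower. RR16 (1.06 ± 0.40) and the epidermal patterning gene TRY (1.07 ± 0.37) did not pass.

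A total of 2445 probesets differed in this comparison, 1122 higher and 1323 lower, with a median shift of -0.14 over all probesets; median centring gave 1683 higher and 560 lower. The remaining large rises were AT1G70820 (19.1-fold), AT5G64110 (17.5-fold), AT5G59490, AT5G37840, AT1G59740 and AT3G13950, and the remaining falls AT5G41680 (7.27-fold), AT1G20540 (7.26-fold), AT5G66310, AT3G25930, AT2G22400, AT5G57840, AT3G04480 and AT1G03560. The count was 1552 without empty vector mock replicate 1 and 1563 without empty vector mock replicate 3. The early auxin list did not pass camera (adjusted p = 0.324), with 2 members lower. On the auxin index both over-expressors lay below the empty vector in mock, by -0.83 for IAA7mII and -0.48 for IAA19mII (exact permutation p = 0.1 each).

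The same comparison after IAA asked how far the populations stand apart once auxin is present. With IAA7mII, IAA29 was 41.0-fold lower than in empty vector cells (-5.36 ± 0.48, limma adjusted p = 4.56e-09), IAA30 17.2-fold lower (-4.10 ± 0.35), GH3.3 13.1-fold lower (-3.71 ± 0.44) and HAT2 9.28-fold lower (-3.21 ± 0.48). CLE44 and WAG2, a protein kinase gene, were each 13.1-fold lower, LBD16 4.86-fold and LBD29 4.16-fold. AT4G18425 was 19.1-fold higher (4.26 ± 0.20), PAP20 16.4-fold higher (4.04 ± 0.24), AT1G26390 15.9-fold higher and RR16 3.66-fold higher. IAA18 (-1.18 ± 0.26), GH3.1 (-1.52 ± 0.47) and WES1 (-1.63 ± 0.17) were lower. XTH19 (-1.34 ± 0.28), EXPA4 (-1.62 ± 0.47) and EXPA8 (-1.07 ± 0.38) were lower too. In IAA7mII cells the mean signal was 73.7 (SD 84.7) for EXPA4 and 4.9 (SD 4.1) for EXPA8. GH3.17 (1.26 ± 0.21) and XTH18 (1.29 ± 0.33) were higher.

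The IAA7mII comparison with IAA called 3288 probesets, 1304 higher and 1984 lower (median shift -0.17; 2210 and 902 after median centring). Its other large rises were AT5G54130 (15.1-fold), AT5G64190 (14.8-fold), AT5G43590, AT2G43880, AT2G22760, AT5G25920 and AT4G22470, and its other falls AT3G25930 (26.8-fold), AT5G57340 (18.5-fold), AT4G37550, AT5G43450, AT4G37380 and AT1G64405. All 8 early auxin genes were lower (camera adjusted p = 1.37e-10, and 0.00102 with an estimated correlation), as was the Aux/IAA list with 3 of 4 members (0.000195, and 0.00432).

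With IAA19mII and IAA, cwINV6 was 75.9-fold higher (6.25 ± 0.35, limma adjusted p = 5.53e-13), AT2G16890 29.3-fold, scpl28 20.8-fold (4.38 ± 0.34), PAP20 16.4-fold and the beta-glucosidase gene BGLU28 16.3-fold (4.02 ± 0.34). IAA29 was 29.5-fold lower (-4.88 ± 0.48), IAA30 19.0-fold lower (-4.25 ± 0.35), CLE44 12.4-fold lower, GH3.3 6.88-fold lower (-2.78 ± 0.44) and HAT2 5.91-fold lower. GH3.17 stood 6.13-fold higher (2.62 ± 0.21) and XTH18 5.58-fold higher, while LBD29 (-2.05 ± 0.35), LBD16 (-1.54 ± 0.41) and WES1 (-0.78 ± 0.17) were lower. In this comparison 3975 probesets differed, 1564 higher and 2411 lower (median shift -0.17; 2347 and 1132 after median centring). The other large rises were AT5G59490 (25.6-fold), AT2G22760, AT4G18425 (18.7-fold), AT5G64110 and AT1G70820, and the other falls AT3G25930 (14.4-fold), AT4G37380, AT5G41680, AT4G37550, AT3G20300, AT1G50510 and AT3G62110. Of the early auxin list 7 members were lower and 8 adjusted over the list alone (camera adjusted p = 2.7e-07, and 0.00527 with an estimated correlation), and the Aux/IAA list had 2 lower members (0.0268, and 0.0592).

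**Figure D3:**
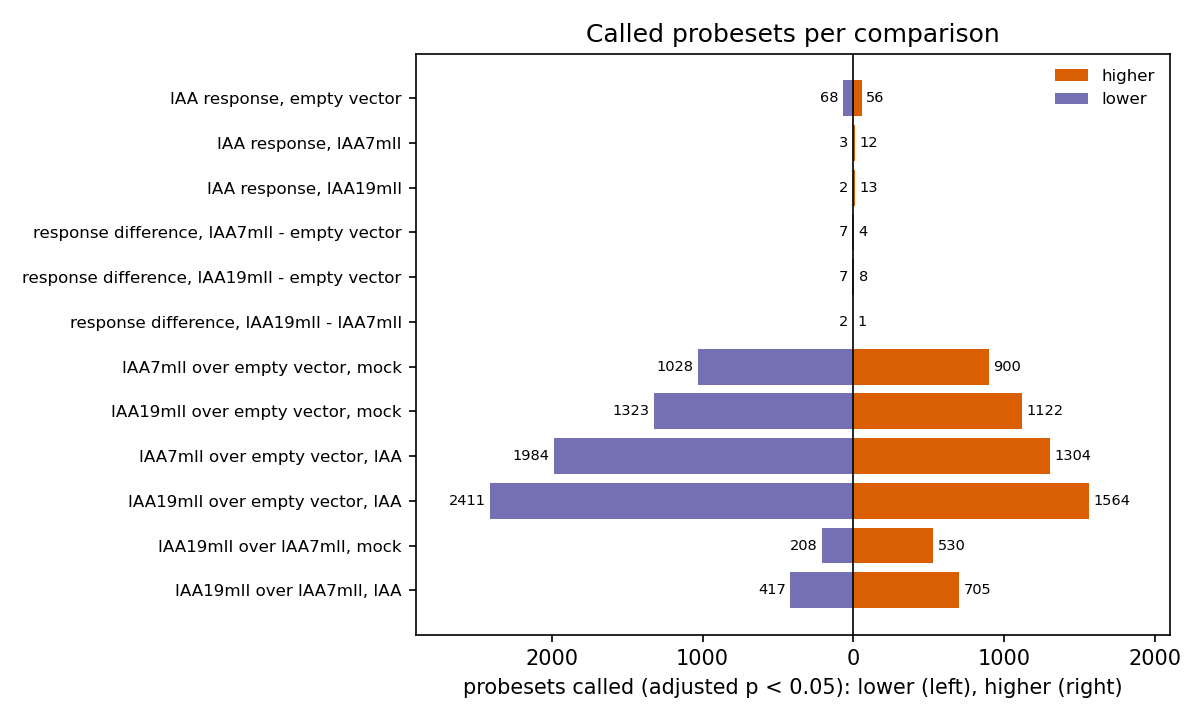
Number of probesets called at a limma adjusted p under 0.05 in each of 12 comparisons of 3 arrays per group, with higher counts to the right of 0 and lower counts to the left. The comparisons with the empty vector hold 1928 to 3975 probesets, and the responses to IAA hold 124, 15 and 15.

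Many changes against the empty vector were called in both over-expressors, among them AT4G18425, scpl28, AT5G41680 and FOLB2 in mock. Calls shared in the same direction made up 57.3% of the IAA7mII calls and 45.2% of the IAA19mII calls in mock, and 60.9% and 50.4% with IAA. In mock 565 probesets were higher in both and 540 lower in both, against 59.8 and 80.5 if the calls were independent. Both comparisons use the same empty vector arrays, which alone gave a correlation of 0.501 across probesets in simulated data without differences between vectors. The observed correlation was 0.677. It also holds the differences between vectors, so the simulated value is not the part of it due to the shared arrays. The covariance was 0.328 observed and 0.0711 simulated. The 50 simulations gave 0 shared calls, but they held no differences between vectors. They therefore cannot show how many of the shared calls come from the common arrays. Across comparisons that share no array, IAA7mII in mock and IAA19mII with IAA, 684 were higher in both and 613 lower in both, against 83.3 and 147. The correlation of these comparisons was 0.633, and that of IAA19mII in mock with IAA7mII with IAA was 0.58.

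The final comparison was between IAA19mII and IAA7mII, which share a plasmid backbone that differs from that of the empty vector. In mock, AT5G64110 was 21.8-fold higher with IAA19mII (4.45 ± 0.35, limma adjusted p = 1.88e-09), cwINV6 13.6-fold (3.76 ± 0.35), AT5G43450 13.5-fold (3.76 ± 0.26) and AT3G59710 13.2-fold (3.73 ± 0.24). ACLA-2, named for a subunit of ATP-citrate lyase, was 4.45-fold lower (-2.16 ± 0.34). The auxin genes WES1 (2.27-fold, 1.18 ± 0.17), GH3.17 (2.45-fold, 1.29 ± 0.21) and LBD16 (2.88-fold, 1.53 ± 0.41) were higher with IAA19mII. In all 738 probesets differed, 530 higher and 208 lower. The GH3 list passed camera (adjusted p = 0.00145, and 0.0229 with an estimated correlation) and the early auxin list did not (0.0838). The auxin index differed by 0.35 in mock and 0.48 with IAA (exact permutation p = 0.3 for each). The other genes with non-overlapping rises were AT1G59740, AT3G22570, AT1G70810 (9.59-fold), AT4G36150, AT5G23840 and AT4G19720, and those with falls AT1G70450, AT5G54130, AT1G33770, AT1G26390, AT5G55050, AT3G56350, AT1G08310, AT1G64500 and AT1G75770, from 4.45-fold to 3.37-fold.

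With IAA, AT1G70820 was 26.4-fold higher in IAA19mII than in IAA7mII cells (4.72 ± 0.44, limma adjusted p = 4.00e-08), AT3G59710 19.4-fold, AT5G64110 16.5-fold, the peroxidase gene PRX52 15.5-fold (3.95 ± 0.46) and MSRB9 12.7-fold. AT1G33770 was 4.7-fold lower (-2.23 ± 0.41), POLD3 3.58-fold and AMS 3.53-fold. IAA18 (2.59-fold), GH3.17 (2.55-fold) and WES1 (1.79-fold) were higher. So were XTH19 (1.29 ± 0.28), EXPA4 (1.71 ± 0.47), XTH18 (1.19 ± 0.33) and EXPA8 (1.25 ± 0.38). EXPA8 signals were low, with means of 4.9 (SD 4.1) in IAA7mII and 33.5 (SD 8.69) in IAA19mII cells. EXPA4 had a mean of 73.7 with a larger SD of 84.7 in IAA7mII cells, against 192 (SD 28) in IAA19mII cells. The expansin and xyloglucan endotransglucosylase list had 4 members called and 6 adjusted over the list alone (median 1.02, camera adjusted p = 0.000351, and 0.0274 with an estimated correlation), and the GH3 list passed too (0.000892, and 0.0251). A total of 1122 probesets differed, 705 higher and 417 lower. Further rises were those of AT2G03740, AT5G43450, AT1G59740, AT1G20490 and AT4G22212, and further falls those of AT1G72890, AT2G02630, AT1G50510, AT2G41710, AT1G05140, AT5G48570 and AT2G29620, each at least 3.44-fold.

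The single kept members of the lists of marker genes showed no called response to IAA. In empty vector cells the root hair gene EXPA7 (0.41 ± 0.52), TRY (0.36 ± 0.37), AGL42 (-0.31 ± 0.39), the photosynthesis gene RCA (0.39 ± 0.43), the heat shock gene ATHSP22.0 (0.35 ± 0.44), the defence gene WRKY53 (1.31 ± 0.44), the detoxification gene GSTU25 (-0.03 ± 0.41) and RR16 (0.14 ± 0.40) did not pass the limma test. Between vectors with IAA present, RCA was lower in IAA7mII (2.38-fold, lost in 10 of 18 other settings) and IAA19mII (4.16-fold) cells, and WRKY53 was 3.46-fold and 4.94-fold lower. TRY was 2.37-fold higher (1.25 ± 0.37, limma adjusted p = 0.0153) and AGL42 2.15-fold higher with IAA19mII, and GSTU25 was 2.59-fold higher in IAA19mII than in IAA7mII cells; other settings lost these calls in 2 of 18, 6 of 19 and 11 of 19 cases. The reference genes PEX4, AT4G34270 and AT2G28390 were not called in any of the 12 comparisons. Adjusted over the list alone, 1 was lower in IAA7mII than in empty vector cells with IAA. Each had a lower value in every comparison with the empty vector: -0.26 to -0.52 for PEX4, -0.24 to -0.62 for AT4G34270 and -0.63 to -0.82 for AT2G28390. The transgenes IAA7 and IAA19 are not named in the annotation used, so their levels were not analysed here, and whether either probeset listed at 0 measures a transgene was not analysed here either.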

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

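The tests of chance by other splits of the arrays and of scaling for the smaller auxin response were planned before the results were seen; the other tests in this part were chosen after. The results below are those whose response to IAA differed between an over-expressor and the empty vector in limma's test of the difference itself.

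With IAA7mII the differences in log2 response were 1.54 for AT3G46700, 1.39 for SFP1, 1.38 for AT1G02360, -4.54 for IAA29, -2.98 for AT1G64405 and -2.73 for IAA30. With IAA19mII they were 1.5 for AT3G46700, 1.38 for SFP1, 1.32 for AT1G02360, 1.16 for OSM34, -4.54 for IAA29, -3.25 for AT4G37380 and -2.84 for IAA30. The positive values belong to genes called lower with IAA in empty vector cells alone, and the negative values to genes that IAA raised in empty vector cells. The groups compared stand at different levels before IAA: SFP1 had a mock mean of 1505 in empty vector, 4146 in IAA7mII and 3461 in IAA19mII cells.

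Other splits of the same arrays were counted for each comparison. For the differences of responses, 9 of 100 splits called as many probesets as the real 11 for IAA7mII against empty vector (highest other 1442), 5 of 100 as many as the real 15 for IAA19mII against empty vector (highest 1793) and 10 of 100 as many as the real 3 for IAA19mII against IAA7mII (highest 350). These shares do not decide on chance, which stays open for these counts. The splits with high counts point to a structure of the samples: a split that exchanges the arrays of the vectors in 1 treatment and not in the other carries the difference between vectors into the difference of responses, so such splits do not stand for an absence of change. For the comparisons of 3 arrays against 3 only 10 splits exist, too few for a share under 0.05, and 1 of 10, the real one, reached the real count in each. The real and highest other counts were 124 and 2 for the response in empty vector cells, 15 and 2 with IAA7mII, 15 and 4 with IAA19mII, 1928 and 0 for IAA7mII against empty vector in mock, 2445 and 0 for IAA19mII, 3288 and 0 for IAA7mII with IAA, 3975 and 0 for IAA19mII with IAA, 738 and 0 for IAA19mII against IAA7mII in mock and 1122 and 6 with IAA.

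The smaller response of auxin-induced genes in over-expressor cells was weighed against 4 technical readings. A larger spread between over-expressor arrays would move members both ways, whereas 8 of 8 responded less in both (7 of 8 with pseudocount 1, and both counts use the same empty vector arrays). These auxin genes rise together and are not independent trials. LBD29 passed the filter only through its empty vector IAA arrays (mean signal 76.8, against 3.57 to 6.93 in every other group). The count is therefore weak evidence. The index differences of -2.15 and -2.02 are several times the largest group SD of 0.45. Scaling leaves the difference of the IAA7mII index at -2.13 after quantile normalization, more than 2 pooled SD of 0.258 below 0 (the planned test had also asked for a permutation p below 0.05, which the mock levels put out of reach in this design). Auxin genes already high before IAA would leave no room to rise, yet the higher of the mock differences is -0.48. The backbone cannot be told apart from the inserted genes, since both over-expressors share it and their responses differ by 0.13. Repression by the stabilised Aux/IAA proteins may underlie the pattern and stays a hypothesis beside the backbone. The empty vector arrays also had higher 75th percentiles (264 to 275) than the over-expressor arrays (220 to 238). Any other difference between the populations that goes with the vector cannot be told apart either and was not tested.

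The many probesets that differ between over-expressor and empty vector cells are not accounted for by scaling alone, since quantile normalization still calls 1792 for IAA7mII in mock. The backbone cannot be told apart here either: 1105 probesets are called the same way in both over-expressors in mock. A biological effect of the proteins common to both could give the same sharing, and the arrays hold no empty pBeaconRFP vector to separate them. A backbone acting alike in both over-expressors would not give the 738 probesets that differ between IAA19mII and IAA7mII in mock. Whether it acted alike, or these populations differed in another way than the inserted gene, was not tested.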

How the results depend on the processing

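One alternative, leaving out the 2 probesets listed at 0, was chosen after the data were seen; the others were planned. No called gene or index value changed sign under an alternative. Some list medians near 0 did, among them that of the expansin and xyloglucan endotransglucosylase list in the empty vector response (0.06 to -0.04 with quantile normalization), and so did some uncalled genes; the uncalled GH3.3 difference of IAA19mII from empty vector went from -1.31 to 0.16 with pseudocount 1. The majority direction of calls did turn with scaling: from mostly lower to mostly higher for both over-expressors against empty vector in mock (931 higher and 861 lower, 1173 and 999 with quantile normalization; 1414 and 537, 1683 and 560 with median centring) and with IAA (2210 and 902, 2347 and 1132 with median centring), and for the IAA7mII response difference (10 and 8 with quantile normalization, 7 and 6 with median centring), and from 8 and 7 to 6 and 7 for that of IAA19mII with quantile normalization. Of values answering a comparison 270 stayed within 1.5 times the count or 1 SD and 63 moved; the cause was not tested. For named genes 7019 gene and setting pairs stayed on their side of the threshold and, if uncalled, within their spread. Another 375 were weaker, 197 of them with an array left out, and 40 stronger. A further 46 uncalled values moved by more than their spread (27 with pseudocount 1, 9 with pseudocount 64, 9 with an array left out, 1 with median centring). For lists 717 stayed on their side, 33 were weaker (28 with the estimated correlation, 5 with quantile normalization) and 6 stronger. Among those that stayed, called genes and lists kept direction, while uncalled ones could change sign. Calls kept in every setting numbered 9 of 25 named genes for the empty vector response, 3 of 6 for IAA7mII, 1 of 6 for IAA19mII, and 0 of 6 and 0 of 7 for their differences from empty vector, against 20 of 26, 21 of 24, 30 of 35 and 28 of 32 for the comparisons with empty vector (mock IAA7mII and IAA19mII, then IAA). Between IAA19mII and IAA7mII they numbered 17 of 23 in mock and 17 of 28 with IAA. The IAA29 differences lost their call, not their size, with pseudocount 1 (-4.99 and -5.32) and lost their call with the unmoderated test; the adjusted p of limma's alternatives ranged from 3.49e-07 to 0.632 for IAA7mII and 4e-07 to 0.432 for IAA19mII. AT4G10270 and AT3G10040 lost their empty vector call with the unmoderated test alone (up to 0.135 and 0.14).

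Without the intensity trend the empty vector response had 66 probesets, the IAA19mII response 8, and the differences from empty vector 7 (IAA7mII), 3 (IAA19mII) and 7 between over-expressors. The unmoderated test gave 69, 4, 5 and 4 for the empty vector response, IAA19mII response and both differences from empty vector. Array weights gave 328 for the empty vector response, 19 and 25 for those differences, 3031 and 3965 for IAA7mII and IAA19mII against empty vector in mock, and 539 for IAA19mII against IAA7mII with IAA. With only the groups of the contrast the IAA7mII response had 8 and IAA19mII against IAA7mII with IAA had 480. Pseudocount 1 gave 5 and 5 for the differences from empty vector, and pseudocount 64 gave 22 and 27; quantile normalization gave 18 for IAA7mII. Without the 2 probesets listed at 0, the difference between over-expressors had 1. The replicate block gave 24 for the IAA19mII response and moved no other count by over 1.5 times, and is an alternative because the replicate numbers pair the arrays weakly if at all: of 45 pairs with the same number 1 had a correlation over 0.1 (-0.06 to 0.16), 43 of 90 best matches bore their own number against 30 by chance, and all 12 pairs between over-expressors lay above 0 (0.00404 to 0.0818). The scan batch alternative was not run, because the batch fields used here are empty.

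The index response in empty vector, IAA7mII and IAA19mII cells was 4.31, 2.24 and 2.40 with pseudocount 1, 2.91, 0.98 and 1.06 with pseudocount 64, 2.46, 1.1 and 1.35 with Aux/IAA and GH3 members only, and 2.61, 1.04 and 1.26 with all early auxin lists; with no filter the empty vector value was 3.35 with 9 members. Leaving out each array gave 78 to 111 for the empty vector response (78 without mock replicate 2, 81 without IAA replicate 2). It gave 11 to 35 for the IAA7mII response (35 without IAA replicate 1). For the IAA19mII response it gave 7 to 20 (8 without mock replicate 1, 7 without mock replicate 2, 8 without IAA replicate 2). The differences of IAA7mII and IAA19mII from empty vector ran from 5 to 10 and from 4 to 15. Only the arrays that moved these counts by over 1.5 times are named with their values above. Between over-expressors the range was 3 to 5 (5 without IAA19mII IAA replicate 1). In mock, IAA7mII and IAA19mII against empty vector gave 1214 to 1635 and 1552 to 2100 (1284 and 1552 without empty vector mock replicate 1, 1214 and 1563 without replicate 3). With IAA they gave 2380 to 3172 and 2827 to 3600. IAA19mII against IAA7mII gave 494 to 603 in mock and 904 to 1049 with IAA. The index response ranged from 3.6 to 3.80, 1.26 to 1.68 (1.26 without IAA7mII IAA replicate 3) and 1.52 to 1.76, and its differences from -2.41 to -1.99 and -2.16 to -1.91. Low signals limit what can be seen: near the pseudocount folds are understated.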

Other observations

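The low-oxygen gene test in this part was chosen after falls with IAA had been seen, and the gene lists in this part were chosen after the annotation was seen; the members named here were chosen after their values were seen. Several beta-glucosidase genes were higher in over-expressor than in empty vector cells. In mock BGLU46 was higher by 1.78 ± 0.15 on the log2 scale with IAA7mII and 1.91 ± 0.15 with IAA19mII, and BGLU41 by 2.19 ± 0.35 and 2.23 ± 0.35. BGLU28 was higher by 2.62 ± 0.34 with IAA19mII and fell by 1.53 with IAA in empty vector cells. BGLU25 was lower with IAA19mII (-1.17 ± 0.25). Of the 15 family members, 5 were higher and 1 lower with each plasmid in mock (limma camera adjusted p = 0.000924 and 0.0006, and 0.0866 and 0.0741 with an estimated correlation). With IAA 5 were higher and 2 lower for IAA7mII (0.000907, and 0.13), and 8 higher and 1 lower for IAA19mII (2.13e-05, and 0.0249), the only one of these to hold with an estimated correlation. The family also passed camera in the empty vector response (0.0067, and 0.15) and in the difference of IAA19mII from it (0.0132, and 0.25).

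Some wound and immune genes were higher with IAA19mII, while the list as a whole did not pass with an estimated correlation and WRKY53 was lower with IAA. CML43, a calmodulin-like gene, was higher than in empty vector cells by 2.54 ± 0.38 in mock and 2.29 ± 0.38 with IAA, WRKY22 by 1.27 ± 0.33 and 1.01 ± 0.33, and GRX480 by 1.40 ± 0.24 and 1.90 ± 0.24. Of 18 list members 4 were higher in mock and 9 higher and 1 lower with IAA (limma camera adjusted p = 0.0082 and 0.000125, and 0.488 and 0.392 with an estimated correlation). Against IAA7mII 3 were higher in mock and 4 with IAA (0.00792 and 0.0136, and 0.549 and 0.339). The autophagy gene ATG8E was higher by 0.79 ± 0.14 with either plasmid in mock and by 1.16 ± 0.14 and 1.12 ± 0.14 with IAA. Its list of 10 passed camera for IAA7mII in mock (0.0109, and 0.656) and with IAA (0.000907, and 0.342) and for IAA19mII with IAA (0.0291, and 0.423). No other member was called in mock with either plasmid. With IAA, APG8A was also called higher with both plasmids and ATG8B with IAA7mII, while ATG8G was called lower with IAA19mII (-0.81 ± 0.29).

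Of 15 genes encoded in the mitochondrion 7 were higher in IAA7mII than in empty vector cells with IAA, nad1 among them (0.63 ± 0.16), and 3 in IAA19mII cells (limma camera adjusted p = 1.97e-05 and 0.0135, and 0.342 and 0.423 with an estimated correlation). That list also passed in mock for IAA7mII (0.0109, and 0.713), in the IAA7mII response (0.00533, and 0.899) and in its difference from empty vector (0.00981, and 0.553). The 66 genes encoded in the plastid had a median change of 0.32 in the empty vector response and 0.33 in the IAA7mII response (0.000269 and 1.02e-06, and 0.659 and 0.899), and passed in the difference between over-expressors (0.0399, and 0.951). The 24 wall remodelling genes passed in the empty vector response (0.0067, and 0.121), where GH9C2 rose, and between over-expressors with IAA (0.0256, and 0.209). The 4 auxin metabolism genes passed in the empty vector response (0.0442, and 0.256). The other 9 lists, of nuclear photosynthesis, glycosyltransferase, glutathione transferase, trichome birefringence-like, sugar transporter, chaperone, endoplasmic reticulum stress, cell division, and dehydration and cold genes, passed camera in none of the 12 comparisons (smallest adjusted p = 0.0562).

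Genes known from low-oxygen responses may fall together with IAA, most in empty vector cells. Several of the largest falls (AT4G10270, AT3G10040, AT1G33055 and AT4G24110) are loci known to respond to low oxygen, so a list of other such loci was written and tested, leaving those 4 out; 1 of the 4 was moved out of the tested list after a first result was known. The 20 remaining members had a median log2 response of -0.99, 17 were lower, and AT1G74940, CML38 and AT3G03270 were called lower by limma (camera p = 7.76e-06 with an estimated correlation). The list fell in the over-expressors as well, by a smaller median: -0.35 in IAA7mII cells, with 15 of 20 lower (limma camera p = 0.0249 with an estimated correlation), and -0.20 in IAA19mII cells, with 16 of 20 lower (0.0275). No member was called in either over-expressor, and these p-values are unadjusted. The differences from the empty vector response were 0.60 and 0.46 (camera p = 0.00328 and 0.00416 with an estimated correlation). The list was written after falls were seen on the empty vector arrays. The empty vector fall and both differences use those arrays, so their p-values are not independent evidence, also with the 4 loci left out. In mock the 20 members already had a median of -0.63 against empty vector with IAA7mII, with 16 lower (limma camera p = 0.0237 with an estimated correlation). The median was -0.21 with IAA19mII, with 15 lower (limma camera p = 0.33 with an estimated correlation). Of the members, AT3G27220 had already been named among the large IAA7mII falls in mock and was not left out. With IAA the medians were -0.02 and 0.16, neither of which passed camera, so with IAA7mII the smaller fall goes with a lower start. The oxygen supply of the cells is not in the labels, and no cause was tested.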
